A study of Mus musculus with 8 samples.

How the data were processed

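Total RNA of 8 samples of mouse bone marrow-derived macrophages was hybridised to Affymetrix mouse gene arrays, 1 sample per array, with a biotin label and RNA integrity above 9, per the labels' protocols. The value table holds 1 value per probe set and array. Its deposited values ran from 1.46 to 13.71 with array medians between 6.12 and 6.20, which is a log2 scale, although the labels name the column as a MAS5 signal, and they were used as log2 signal without a further log. The log2 scale was read from the values, and the authors' background correction and normalization between arrays are not given in the sources used here. The arrays came without detection calls, so the values show no level below which a gene is absent. The stated precision rests on 2 arrays per group and leaves out the effect of the normalization chosen. No column of the table lay outside the 8 samples.

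Gene names came from the platform annotation, which can be old. Of 35556 probe sets, 21789 carried 1 gene symbol, 1621 carried several and 12146 carried none in that annotation. Entrez identifiers of 21698 probe sets were found in the RefSeq gene table of assembly GRCm38.p6, and 0 symbols needed an update. Named genes numbered 19938, and for the 999 genes with more than 1 probe set the one with the highest mean over all 8 arrays stood for the gene. Probe sets with several symbols or none were left out of the comparisons and are reported in the closing section. The BC023105 probe set is named as the annotation gives it.

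Groups were taken from the sample labels. A single model over the 4 groups was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes with a mean-variance trend), with 4 residual and 7.55 prior degrees of freedom. Each of the 6 comparisons was adjusted by Benjamini-Hochberg over the 19938 named genes, and a gene was called at an adjusted p under 0.05. A gene was highest or lowest under LPS/IL-4/IL-13 where all 3 comparisons of that group passed in the same direction. The test, its samples, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined.

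The text names, per comparison, the 6 genes with the highest and the 6 with the lowest log2 fold change among called genes whose 2 groups did not overlap, leaving out predicted genes and small RNAs. It also names 17 markers of macrophage activation whatever their value, up to 4 members per gene list with the largest called change and up to 2 that did not pass, and the 10 genes with the widest margins in each direction for the combination. Examples in the paragraphs on shared genes, and the genes of the lists added later, were picked from the results by eye. The 25 gene lists cover interferon, NF-kB, STAT6 and feedback genes, growth factors, antigen presentation, phagocytosis, lipid, glucose, arginine, matrix, chemoattractant receptor, cell cycle and macrophage identity genes, and markers of 7 other cell types. They held 445 genes, of which 399 were measured. Each list was tested in each comparison with limma's camera at a preset correlation of 0.01, adjusted over the 150 tests, again with an estimated correlation, and with fry. Camera called 63 of the 150 tests, of which 13 held with an estimated correlation. That form also uses at most the 4 residual degrees of freedom, so its p-values reflect more than correlation within a list. Fry, which asks only whether a list's genes move one way, called 117, and its mixed form, which asks whether they change in either direction, called 140. Neither compares a list with other genes.

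The fit was tested on simulated data, with normal noise at the estimated spread of 19938 genes and a seeded set of changed genes. In IFN-gamma/LPS against untreated it found 47.8% of true log2 changes of 0.5, 100% of 1 and 100% of 2, with 12 false calls. The shares were 53.7%, 98.5% and 100% with 12 false calls for IL-4/IL-13 against untreated, and 55.2%, 98.5% and 100% with 12 for LPS/IL-4/IL-13 against untreated. LPS/IL-4/IL-13 against IFN-gamma/LPS gave 63.6%, 99.2% and 100% with 21 false calls, LPS/IL-4/IL-13 against IL-4/IL-13 gave 69.7%, 99.3% and 100% with 21, and IFN-gamma/LPS against IL-4/IL-13 gave 63.9%, 99.2% and 100% with 21. The rule of 3 tests found 156 of 192 simulated genes with 2 false calls. With the cell cycle list alone shifted by 0.5 in the IL-4/IL-13 group, camera found it in all 3 comparisons with that group. The noise was independent across genes, so this says nothing of camera on correlated lists. In that setting, true changes of 0.5 on the log2 scale were often missed. The simulation changed 200 genes per treatment, far fewer than were called in the data. Its shares and false calls therefore do not carry over to the data.

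Alternatives were quantile normalization, median centring, a filter on dim probe sets at the 40th percentile, other variance models, only the 4 arrays compared, the replicate number as a block, the mean over probe sets, a fold of at least 2, adjustment over all 6 comparisons, and leaving out each array. Cyclic loess normalization, a crossed block and adding the probe sets with several symbols were chosen after seeing the data. Shared untreated arrays were simulated with unchanged groups, 100 times for the correlation and covariance and 20 times for the calls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.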

Results

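Gene expression was measured in mouse bone marrow-derived macrophages, phagocytes grown in culture from bone marrow cells, on 8 Affymetrix mouse gene arrays. The cells were left untreated or were treated for 6 h with IFN-gamma and LPS (a bacterial cell wall component sensed by Toll-like receptor 4), with IL-4 and IL-13, or with LPS, IL-4 and IL-13 together, and each of the 4 groups had 2 arrays. The stated aim was to find the activation state and the gene signature that each treatment gave. No sample received LPS alone or IFN-gamma alone, so the 2 groups with LPS differed both in IFN-gamma and in IL-4 and IL-13. Array medians lay between 6.12 and 6.20 on the log2 scale, and the values ran from 1.46 to 13.71. Replicate arrays correlated across genes, which are not independent replicates, at r = 0.9974 (untreated), 0.9939 (IFN-gamma/LPS), 0.9961 (IL-4/IL-13) and 0.9941 (LPS/IL-4/IL-13). The first principal component held 76.9% of the variance and separated both groups with LPS from the other 2 groups, and the second held 10.9% and separated both groups with IL-4/IL-13 from the rest. Nothing in the labels says that the 2 arrays of a group came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical. Changes are given as log2 fold changes ± SE from limma with n = 2 arrays per group, and a gene rose or fell where its limma adjusted p was under 0.05 over the 19938 named genes.

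**Figure D1:**
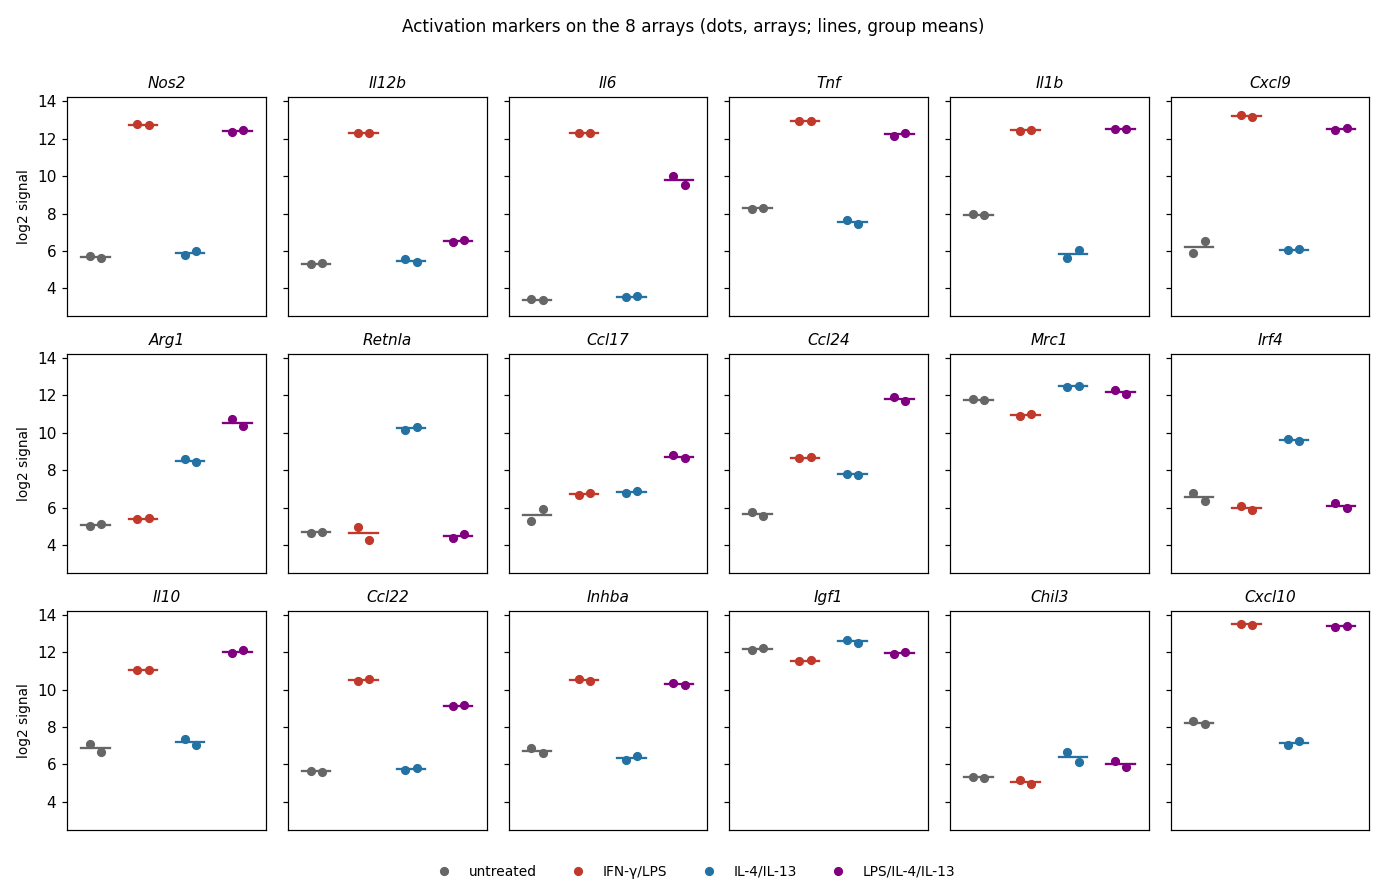
Log2 signal (vertical axis) of 18 genes on each of the 8 arrays, 1 point per array and 4 groups per panel, with a line at each group mean. Nos2 stood at 5.67 untreated, 12.75 under IFN-gamma/LPS, 5.89 under IL-4/IL-13 and 12.39 under LPS/IL-4/IL-13, while Arg1 stood at 5.07, 5.41, 8.52 and 10.55 in the same order.

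Macrophages given IFN-gamma and LPS raised inflammatory cytokine and interferon-response genes far above untreated cells. Il6, a pyrogenic cytokine, rose 476-fold (log2 8.90 ± 0.14, adjusted p = 8.15e-13), and Nos2, the inducible nitric oxide synthase, rose 135-fold (7.08 ± 0.10). The other largest increases were BC023105 (7.51 ± 0.15), the guanylate-binding protein gene Gbp4 (7.29 ± 0.15), the alarmin gene Il1a (7.15 ± 0.16) and the activation marker gene Cd69 (7.05 ± 0.10). Sesn1, a p53-inducible stress gene, fell 32.1-fold (-5.01 ± 0.15), followed by the Ras activator gene Rasgrp3 (-4.57 ± 0.10), the peroxisomal transporter gene Abcd2 (-4.56 ± 0.12), Nfam1 (-4.55 ± 0.10), the iron exporter gene Slc40a1 (-4.53 ± 0.11) and Otulinl (-4.49 ± 0.14). In limma, 4701 genes were higher and 5656 lower, 51.9% of the genes tested, and 1165 and 2230 of them changed at least 2-fold. Without untreated array 1, the higher genes numbered 2936.

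All 29 measured NF-kB-driven cytokines, chemokines and regulators rose, among them Il12b (6.98 ± 0.10), which encodes the shared subunit of IL-12 and IL-23, the cyclooxygenase gene Ptgs2 (6.38 ± 0.09), Tnf (4.67 ± 0.08) and Il1b (4.51 ± 0.11), with camera adjusted p = 1.09e-19, and adjusted p = 0.0167 with an estimated correlation. Of 14 IFN-gamma-inducible GTPases and regulators, 13 rose, including Cxcl9 (6.98 ± 0.15), Cxcl10 (5.26 ± 0.09) and Gbp5 (6.49 ± 0.09), with camera adjusted p = 3.94e-13, and adjusted p = 0.0205 with an estimated correlation. All 27 interferon-stimulated antiviral genes rose, led by Mx1 (5.27 ± 0.11), Ifit2 (4.70 ± 0.10) and Mx2 (4.52 ± 0.15). That list had camera adjusted p = 2.07e-21, and adjusted p = 0.177 with an estimated correlation. Among feedback regulators, 14 of 19 rose and 3 fell, with Acod1, the itaconate-producing enzyme gene, at 6.86 ± 0.14, Socs3 at 5.16 ± 0.10 and Il10 at 4.17 ± 0.14 (camera adjusted p = 2.38e-06, and adjusted p = 0.0529 with an estimated correlation). Of 29 genes tied to IL-4/IL-13 and STAT6, 13 rose and 7 fell. The arginine transporter gene Slc7a2 (5.19 ± 0.08) and the chemokine genes Ccl22 (4.86 ± 0.10) and Ccl24 (3.03 ± 0.11) were among those that rose, Arg1 rose by 0.34 ± 0.12, and Ccl17 by 1.13 ± 0.17. The mannose receptor gene Mrc1 fell (-0.82 ± 0.08), while Retnla (-0.05 ± 0.19, adjusted p = 0.853) and Chil3 (-0.26 ± 0.17, adjusted p = 0.219) did not pass.

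Antigen presentation and trophic genes under IFN-gamma/LPS went in both directions. In the MHC class I list 10 of 12 genes rose, led by the peptide transporter gene Tap1 (2.93 ± 0.07) and its regulator Nlrc5 (2.29 ± 0.10), with camera adjusted p = 2.26e-06, and adjusted p = 0.142 with an estimated correlation. In the MHC class II and costimulation list 4 of 12 rose and 6 fell, with the costimulatory genes Cd40 (5.26 ± 0.07) and Cd86 (3.81 ± 0.10) up and H2-Aa (-0.51 ± 0.09) down, so that the median of the list (-0.12) and its mean (0.76) differed in sign. Growth and trophic factor genes split into 11 that rose and 9 that fell of 27. Csf1 (3.87 ± 0.09) and the activin subunit gene Inhba (3.80 ± 0.11) rose, and Pdgfb (-2.32 ± 0.10) and Igf1 (-0.62 ± 0.07) fell. The matrix and protease list had 9 of 18 genes up and 5 down, with Mmp13 at 5.65 ± 0.09 and Serpinb2 at 5.10 ± 0.12. Chemoattractant receptors split evenly, 6 up and 6 down of 13, with Ccrl2 (4.70 ± 0.09) and P2ry13 (3.97 ± 0.09) up and Cxcr4 (-3.89 ± 0.08) down, and there the median (-0.25) and the mean (0.64) had opposite signs. Phagocytosis, scavenger and complement genes also split, 11 up and 13 down of 29, with the Fc receptor gene Fcgr4 (2.09 ± 0.06) up and the scavenger receptor gene Stab1 (-2.67 ± 0.08) down.

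Cell cycle, fatty acid oxidation and sterol synthesis genes mostly fell under IFN-gamma/LPS, and glycolysis genes mostly rose. Of 24 cell cycle genes 20 fell and 2 rose, those that fell including the cyclin gene Ccna2 (-3.07 ± 0.14) and the mitotic kinase gene Plk1 (-2.58 ± 0.15), with camera adjusted p = 5.03e-07, and adjusted p = 0.235 with an estimated correlation. In the fatty acid oxidation and TCA cycle list 16 of 21 fell and 2 rose, the falls led by Idh1 (-3.72 ± 0.09) and the acyl-CoA dehydrogenase gene Acadm (-2.62 ± 0.13), with camera adjusted p = 5.19e-05, and adjusted p = 0.315 with an estimated correlation. Idh1 is on that list, but it encodes the cytosolic isocitrate dehydrogenase, not an enzyme of the TCA cycle. In the sterol synthesis list 12 of 15 fell and 1 rose, the falls led by Msmo1 (-2.09 ± 0.12) and Dhcr7 (-1.46 ± 0.11), with camera adjusted p = 0.000849, and adjusted p = 0.141 with an estimated correlation. The LXR and cholesterol efflux list had 8 of 15 down, with the efflux transporter gene Abca1 at -3.38 ± 0.08, and 3 up, with the 25-hydroxycholesterol-producing enzyme gene Ch25h at 5.56 ± 0.09 (camera adjusted p = 0.0436, and adjusted p = 0.441 with an estimated correlation). Glycolysis genes had 12 of 19 up and 2 down, led by Pfkp (2.81 ± 0.07), Hk3 (2.66 ± 0.08) and Hk2 (2.03 ± 0.15), with camera adjusted p = 0.00326, and adjusted p = 0.273 with an estimated correlation. Arginine and polyamine genes had 6 of 10 up and 4 down, with Odc1 at 2.32 ± 0.09 and Arg2 at 2.27 ± 0.16. Macrophage identity genes had 10 of 14 down and 3 up, with Cebpa at -2.43 ± 0.11 and Csf1r at -1.09 ± 0.05 (camera adjusted p = 0.0498, and adjusted p = 0.328 with an estimated correlation). Adjusted over the list alone, the counts of members that rose or fell were the same in 21 of the 25 lists and differed by at most 2 genes in the other 4. Bright genes fell often in general, 1123, 1165 and 986 of 1994 genes in deciles 7, 8 and 9 of mean signal. Above the median untreated level lay 23 of 24 cell cycle, 21 of 21 fatty acid oxidation and TCA cycle and 13 of 15 sterol genes. So did 12 of 15 LXR and 14 of 14 identity genes. Camera did not match genes by signal level, so part of these falls may follow that level.

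Marker genes of other cell types moved beside these groups. Of 10 dendritic cell markers 7 rose and 1 fell, with Ccr7 (2.94 ± 0.13), Fscn1 (2.64 ± 0.13) and Xcr1 (2.25 ± 0.14) highest, and the list had camera adjusted p = 0.00952, and adjusted p = 0.169 with an estimated correlation. Activated macrophages can express Ccr7 and Fscn1 too, and 2 of the 10 markers are also in another list. Among 9 mast cell and basophil markers 2 rose, and 1 of them, the histidine decarboxylase gene Hdc (3.65 ± 0.13), stood far above the other, Gata2 (0.38 ± 0.11). Among 12 fibroblast markers 2 rose, Dcn (1.37 ± 0.11) and Pdgfrb (0.62 ± 0.14), and 2 fell, Sparc (-0.44 ± 0.09) and Bgn (-0.41 ± 0.08). Of 14 neutrophil markers 3 fell, the largest being Mmp8 (-0.78 ± 0.10). B lymphocyte markers had 1 of 8 up (0 when adjusted over the list alone), Vpreb3 (0.35 ± 0.13), and 1 down, Cd79b (-1.12 ± 0.12). T and NK markers had 2 of 10 up (Ncr1 0.46 ± 0.14, Nkg7 0.29 ± 0.11), and 0 when adjusted over the list alone. Erythroid markers had 2 of 5 up (Slc4a1 0.43 ± 0.12, Epb42 0.42 ± 0.14). In untreated cells 0 of the T and NK and 0 of the erythroid markers lay above the median level of all genes. Genes among the dimmest 40% of all genes made 1540 of the 4701 higher calls, and 461 dim genes were called higher in a separate fit after quantile normalization. The median of all genes stood 0.105 above the untreated arrays.

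Macrophages given IL-4 and IL-13 changed fewer genes and by smaller amounts, with several genes of alternative activation among the largest increases. Rasgrp1, a Ras activator, rose 59.5-fold (log2 5.90 ± 0.12, adjusted p = 5.45e-11), Retnla, the gene of the secreted protein RELM-alpha, rose 47.0-fold (5.56 ± 0.19), and Pdcd1lg2, the gene of the inhibitory ligand PD-L2, rose 37.3-fold (5.22 ± 0.11). Tarm1 (4.68 ± 0.13), Slc7a2 (4.34 ± 0.08) and Apol7c (4.16 ± 0.18) followed. Slc40a1 fell 9.16-fold (-3.20 ± 0.11), and Stk17b (-2.41 ± 0.14), the integrin gene Itga6 (-2.30 ± 0.12), Lhfpl2 (-2.21 ± 0.11), the monocyte chemokine receptor gene Ccr2 (-2.15 ± 0.13) and Reps2 (-2.13 ± 0.12) fell less. In limma, 1561 genes were higher and 2459 lower, 20.2% of the genes tested, and 213 and 274 changed at least 2-fold. Genes among the dimmest 40% made 296 of the higher calls, and 59 dim genes were called higher in the fit after quantile normalization.

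Of the 29 genes tied to IL-4/IL-13 and STAT6, 23 rose and 6 did not pass, with camera adjusted p = 3.23e-23, and adjusted p = 0.0205 with an estimated correlation. Arg1 rose 10.9-fold (3.45 ± 0.12). Socs2 rose by 3.87 ± 0.15, the transcription factor gene Irf4 by 3.06 ± 0.15, Ccl24 by 2.13 ± 0.11, Ccl17 by 1.20 ± 0.17, Chil3 by 1.10 ± 0.17 and Mrc1 by 0.72 ± 0.08, while Ccl22 did not pass (0.11 ± 0.10, adjusted p = 0.465). Among the IFN-gamma-inducible GTPases and regulators 8 of 14 rose and 1 fell, led by the cytokine signalling inhibitor gene Socs1 (3.74 ± 0.12) and Gbp5 (2.06 ± 0.09), with camera adjusted p = 1.58e-05, and adjusted p = 0.0733 with an estimated correlation. The MHC class I list had 8 of 12 up (10 when adjusted over the list alone), led by the immunoproteasome gene Psmb10 (1.54 ± 0.08), with camera adjusted p = 6.15e-06, and adjusted p = 0.142 with an estimated correlation. The MHC class II list had 3 of 12 up, with Cd40 at 2.74 ± 0.07, and 1 down, Cd80 (-1.09 ± 0.10). Of 29 NF-kB-driven genes 11 fell and 5 rose, with Il1b (-2.11 ± 0.11), Nfkbiz (-2.07 ± 0.08) and Cxcl2 (-1.60 ± 0.15) down and Tnf at -0.72 ± 0.08. That list's median was 0.05, its mean -0.25 and its camera direction down, with camera adjusted p = 0.0498, and adjusted p = 0.206 with an estimated correlation. Cxcl10 fell (-1.07 ± 0.09), and Nos2 (0.22 ± 0.10), Il6 (0.14 ± 0.14), Il12b (0.16 ± 0.10), Cxcl9 (-0.15 ± 0.15) and Il10 (0.34 ± 0.14) did not pass.

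Other groups moved modestly under IL-4/IL-13. Interferon-stimulated genes had 8 of 27 up, led by Zbp1 (1.49 ± 0.09) and Irf7 (1.33 ± 0.08), and 6 down. Phagocytosis, scavenger and complement genes had 13 of 29 down, with the engulfment receptor gene Mertk at -1.51 ± 0.08 and Msr1 at -1.13 ± 0.07, and 4 up, with the inhibitory Fc receptor gene Fcgr2b at 1.53 ± 0.06 (camera adjusted p = 0.00192, and adjusted p = 0.273 with an estimated correlation). Macrophage identity genes had 6 of 14 down and 1 up, with the LPS co-receptor gene Cd14 at -1.42 ± 0.08 (camera adjusted p = 0.00216, and adjusted p = 0.206 with an estimated correlation). Chemoattractant receptors had 6 of 13 down and 1 up (camera adjusted p = 0.00254, and adjusted p = 0.142 with an estimated correlation). Arginine and polyamine genes had 6 of 10 up and 2 down (camera adjusted p = 0.0011, and adjusted p = 0.236 with an estimated correlation). Cell cycle genes had 5 of 24 down (camera adjusted p = 0.00127, and adjusted p = 0.383 with an estimated correlation). Feedback regulators had 7 of 19 up and 4 down, with Nfil3 at 3.01 ± 0.08. Fatty acid oxidation and TCA cycle genes had 3 of 21 up and 4 down, and the increase in the coactivator gene Ppargc1b was 2.62 ± 0.11. Growth factor genes had 6 of 27 up, with Nrg1 (1.88 ± 0.12), Pdgfa (1.34 ± 0.10) and Igf1 (0.41 ± 0.07), and 8 down, with Hgf (-1.41 ± 0.10). Of the markers of other cell types, Hdc rose (1.21 ± 0.13), as did the dendritic cell markers Kmo (1.09 ± 0.11) and Cd209a (0.56 ± 0.11), the NK markers Ncr1 (0.45 ± 0.14) and Nkg7 (0.39 ± 0.11) and the neutrophil precursor marker Mpo (0.44 ± 0.11). Of the 10 T and NK markers, 0 lay above the median untreated level of all genes. The fibroblast marker Sparc fell (-0.34 ± 0.09). Adjusted over the list alone, counts differed in 10 of the 25 lists, by at most 2 genes. In deciles 8, 9 and 10 of mean signal 513, 517 and 498 of 1994 genes fell, and camera did not match genes by signal level. Median centring of the arrays moved the share of changed genes that were higher from 38.8% to 28.6%. The count of 4020 changed genes fell to 2063 without untreated array 1, to 2380 without untreated array 2 and to 2244 without IL-4/IL-13 array 2. The 1561 higher genes numbered 806, 838 and 872 in these fits and 1005 without IL-4/IL-13 array 1, and the 2459 lower ones 1257, 1542 and 1372 in the same 3 fits. In a fit of only the 4 arrays compared, 2455 genes were higher.

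Macrophages given LPS together with IL-4 and IL-13 raised inflammatory genes and alternative activation genes in the same samples. Against untreated cells, Il1a rose 240-fold (log2 7.91 ± 0.16, adjusted p = 3.77e-12), Slamf1, a receptor on activated leukocytes, rose 180-fold (7.50 ± 0.12), and Olr1, an oxidised LDL receptor gene, rose 145-fold (7.18 ± 0.10). Acod1 (6.81 ± 0.14), Nos2 (6.73 ± 0.10) and the endothelin gene Edn1 (6.68 ± 0.09) followed, and Arg1 rose 44.6-fold (5.48 ± 0.12). Slc40a1 fell 32.3-fold (-5.02 ± 0.11), with Rasgrp3 (-4.82 ± 0.10), Sesn1 (-4.67 ± 0.15), the beta-arrestin gene Arrb1 (-4.56 ± 0.11), the phosphodiesterase gene Pde3b (-4.37 ± 0.10) and Pdcd4 (-4.31 ± 0.10) next. In limma, 4042 genes were higher and 5057 lower, 45.6% of the genes tested, and 1032 and 1736 changed at least 2-fold. The higher genes fell to 2602 without untreated array 1. Genes among the dimmest 40% made 1084 of the higher calls, and 378 dim genes were called higher in the fit after quantile normalization.

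Of 29 NF-kB-driven genes 27 rose, with Il6 (6.37 ± 0.14), Il1b (4.61 ± 0.11), Tnf (3.96 ± 0.08) and Il12b (1.22 ± 0.10), and the list had camera adjusted p = 5.16e-21, and adjusted p = 0.0167 with an estimated correlation. All 27 interferon-stimulated genes rose, led by Mx1 (5.15 ± 0.11) and Ifit2 (4.66 ± 0.10), with camera adjusted p = 7.65e-24, and adjusted p = 0.169 with an estimated correlation. Of 14 IFN-gamma-inducible GTPases and regulators 13 rose, with Cxcl9 (6.30 ± 0.15), Cxcl10 (5.16 ± 0.09) and Gbp5 (6.22 ± 0.09), and 1 fell, the class II transactivator gene Ciita (-0.88 ± 0.11), with camera adjusted p = 9.35e-13, and adjusted p = 0.0205 with an estimated correlation. Of the 29 STAT6-linked genes 18 rose (19 when adjusted over the list alone) and 6 fell, with Slc7a2 (6.26 ± 0.08), Ccl24 (6.15 ± 0.11), Pdcd1lg2 (5.78 ± 0.11), Ccl22 (3.51 ± 0.10) and Ccl17 (3.11 ± 0.17) up and camera adjusted p = 2.26e-06, and adjusted p = 0.133 with an estimated correlation. Chil3 (0.71 ± 0.17) and Mrc1 (0.44 ± 0.08) rose a little, and Retnla stood at the untreated level (-0.19 ± 0.19, adjusted p = 0.425). Feedback regulators had 15 of 19 up and 2 down, with Socs3 at 5.57 ± 0.10 and Il10 at 5.15 ± 0.14 (camera adjusted p = 1.22e-09, and adjusted p = 0.0301 with an estimated correlation). Growth factor genes had 11 of 27 up and 11 down, with the EGF-family gene Hbegf (5.23 ± 0.10), Timp1 (4.12 ± 0.11), Inhba (3.56 ± 0.11) and Nrg1 (3.48 ± 0.12) up and Igf1 at -0.21 ± 0.07. Matrix and protease genes had 9 of 18 up and 3 down, led by Mmp13 (5.79 ± 0.09) and Mmp14 (5.02 ± 0.10), with camera adjusted p = 0.00276, and adjusted p = 0.235 with an estimated correlation. Arginine and polyamine genes had 6 of 10 up and 3 down, with Arg2 at 4.17 ± 0.16 (camera adjusted p = 0.00827, and adjusted p = 0.301 with an estimated correlation).

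Cell cycle genes had 21 of 24 down, led by Ccna2 (-2.34 ± 0.14), with camera adjusted p = 2.88e-08, and adjusted p = 0.2 with an estimated correlation. The fatty acid oxidation and TCA cycle list had 16 of 21 down, led by the cytosolic enzyme gene Idh1 (-2.54 ± 0.09), with camera adjusted p = 6.66e-05, and adjusted p = 0.319 with an estimated correlation. Sterol synthesis genes had 10 of 15 down (11 when adjusted over the list alone), led by Dhcr7 (-1.45 ± 0.11), with camera adjusted p = 0.00684, and adjusted p = 0.159 with an estimated correlation. The LXR and cholesterol efflux list had 10 of 15 down and 2 up (camera adjusted p = 0.00513, and adjusted p = 0.306 with an estimated correlation). Glycolysis genes split into 9 up, led by Pfkfb3 (2.63 ± 0.10), and 7 down of 19. Phagocytosis genes split into 11 up, led by the scavenger receptor gene Msr1 (2.23 ± 0.07), and 13 down of 29. MHC class I genes had 10 of 12 up, with Tap1 at 2.43 ± 0.07 (camera adjusted p = 6.37e-07, and adjusted p = 0.142 with an estimated correlation). MHC class II genes had 3 of 12 up and 3 down, with Cd40 at 4.84 ± 0.07. Dendritic cell markers had 5 of 10 up (6 when adjusted over the list alone), with Kmo at 2.30 ± 0.11 and Clec9a at 1.83 ± 0.14 (camera adjusted p = 0.00313, and adjusted p = 0.142 with an estimated correlation). Among markers of other cells, Hdc (4.51 ± 0.13), Dcn (1.75 ± 0.11) and the neutrophil gene S100a8 (1.16 ± 0.20) also rose. Neutrophil markers had 2 of 14 up and 2 down, mast cell and basophil markers 2 of 9 up, fibroblast markers 2 of 12 up and 2 down, and erythroid markers 2 of 5 up. Adjusted over the list alone, counts differed in 5 of the 25 lists, by at most 1 gene. In deciles 7, 8 and 9 of mean signal 1024, 984 and 842 of 1994 genes fell, and camera did not match genes by signal level.

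**Figure D2:**
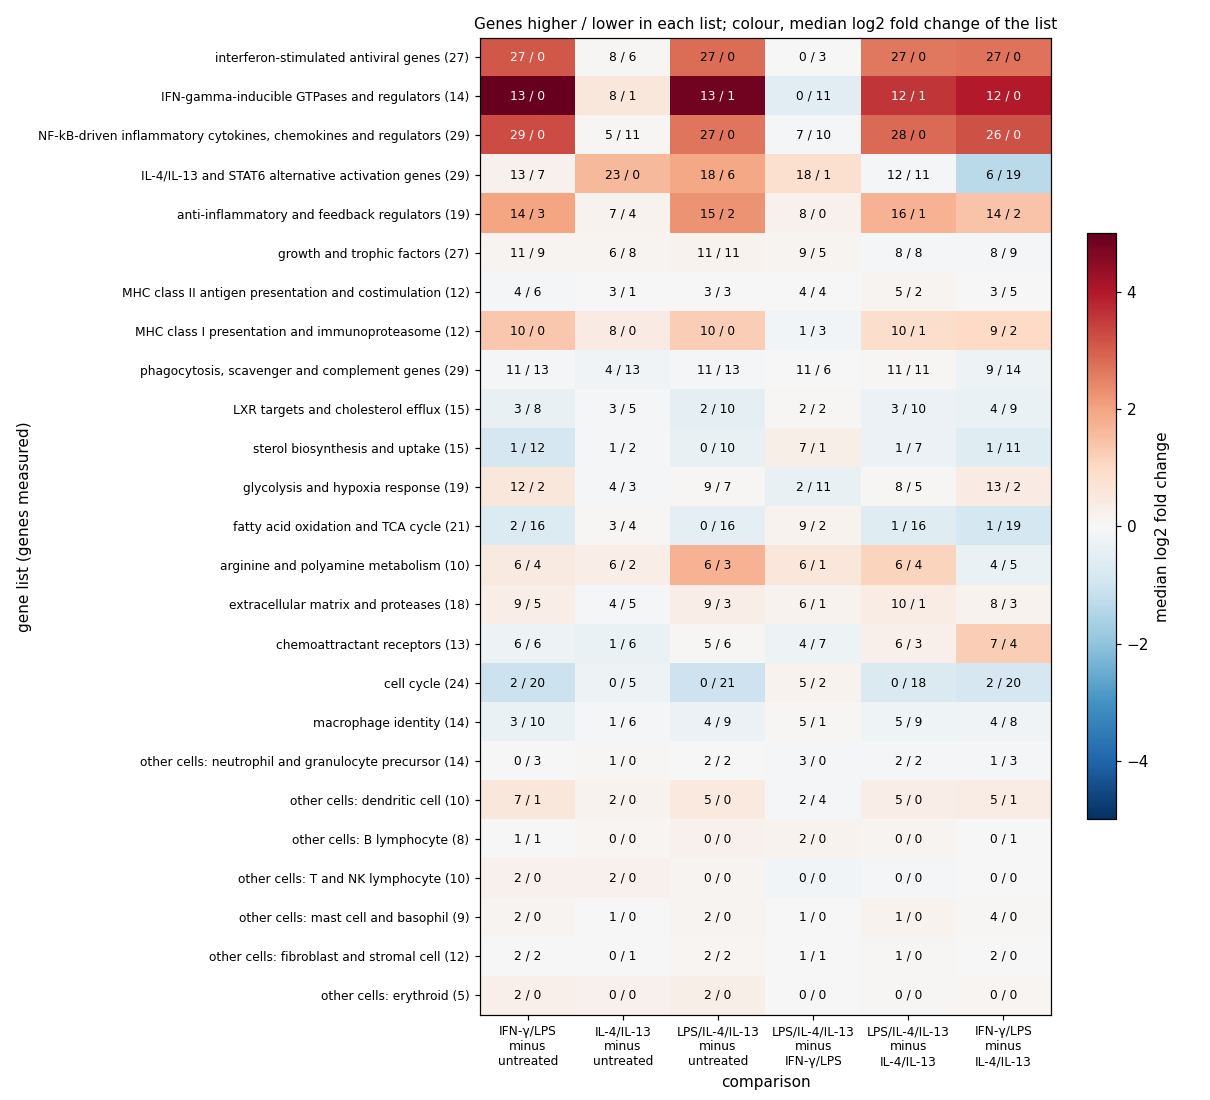
Counts of genes that were higher (before the slash) and lower (after it) in each of 25 gene lists, one line of the grid per list and one column per comparison, with the colour giving the median log2 fold change of the list's measured genes. Against untreated cells, the NF-kB-driven list had 29 genes higher under IFN-gamma/LPS and 27 under LPS/IL-4/IL-13. The STAT6-linked list had 23 higher under IL-4/IL-13, 18 under LPS/IL-4/IL-13 and 13 under IFN-gamma/LPS.

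Set directly against IFN-gamma/LPS, the cells given LPS, IL-4 and IL-13 carried more transcript of alternative activation genes and much less of the IL-12 genes. Arg1 was 35.3-fold higher (log2 5.14 ± 0.12, adjusted p = 4.93e-10), followed by Zfp459 (4.25 ± 0.14), the IL-10 family cytokine gene Il19 (4.19 ± 0.13), Plekhf1 (3.68 ± 0.14), Pdcd1lg2 (3.56 ± 0.11) and Tmem26 (3.43 ± 0.11). Il12b was 54.2-fold lower (-5.76 ± 0.10, adjusted p = 2.57e-11), followed by Cytip (-4.35 ± 0.17), the nuclease gene Dnase1l3 (-3.48 ± 0.11), Prrg4 (-3.45 ± 0.11), the IL-12 signalling gene Stat4 (-3.30 ± 0.13) and the activin-binding protein gene Fst (-3.18 ± 0.10). In limma, 2407 genes were higher and 1519 lower, 19.7% of the genes tested, and 334 and 325 differed at least 2-fold. Leaving out IFN-gamma/LPS array 1 left 1558 higher genes.

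Of the 29 STAT6-linked genes 18 were higher and 1 lower, with the VEGF receptor gene Flt1 (3.26 ± 0.12), Ccl24 (3.13 ± 0.11), Ccl17 (1.99 ± 0.17), Mrc1 (1.25 ± 0.08) and Chil3 (0.97 ± 0.17) higher. Ccl22 was lower (-1.36 ± 0.10), and the list had camera adjusted p = 2.86e-11, and adjusted p = 0.0529 with an estimated correlation. Retnla did not differ past the test (-0.15 ± 0.19, adjusted p = 0.721). Among IFN-gamma-inducible GTPases and regulators 11 of 14 were lower (12 when adjusted over the list alone), led by Gbp4 (-1.84 ± 0.15) and the transcription factor gene Irf1 (-1.14 ± 0.08), with camera adjusted p = 2.52e-09, and adjusted p = 0.0321 with an estimated correlation. NF-kB-driven genes split, 10 lower and 7 higher of 29. Il6 (-2.53 ± 0.14) and Il12a (-1.72 ± 0.12) were lower, the neutrophil chemoattractant gene Cxcl3 (2.57 ± 0.15) was higher, Tnf (-0.71 ± 0.08) and Nos2 (-0.36 ± 0.10) were slightly lower, and Il1b did not pass (0.10 ± 0.11, adjusted p = 0.698). Interferon-stimulated genes had 3 of 27 lower (2 when adjusted over the list alone), the largest being Oas3 (-0.37 ± 0.11), and Cxcl10 did not pass (-0.11 ± 0.09). Feedback regulators had 8 of 19 higher (9 when adjusted over the list alone), with the haem oxygenase gene Hmox1 (1.54 ± 0.08) and Il10 (0.99 ± 0.14), and camera adjusted p = 0.00254, and adjusted p = 0.142 with an estimated correlation. Arginine and polyamine genes had 6 of 10 higher and 1 lower, with Arg2 at 1.90 ± 0.16 (camera adjusted p = 2.19e-05, and adjusted p = 0.17 with an estimated correlation).

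Growth factor genes had 9 of 27 higher and 5 lower, with Hbegf (3.19 ± 0.10), Pdgfa (1.42 ± 0.10) and Igf1 (0.42 ± 0.07) higher and the bone morphogenetic protein gene Bmp2 (-2.31 ± 0.10) and Csf1 (-1.80 ± 0.09) lower. Glycolysis genes had 11 of 19 lower and 2 higher, with Pfkp at -1.03 ± 0.07 and Hk2 at -1.01 ± 0.15 (camera adjusted p = 7.07e-06, and adjusted p = 0.169 with an estimated correlation). In the fatty acid oxidation and TCA cycle list 9 of 21 were higher and 2 lower, with Idh1 at 1.18 ± 0.09 (camera adjusted p = 0.0342, and adjusted p = 0.578 with an estimated correlation). Sterol synthesis genes had 7 of 15 higher and 1 lower, with Msmo1 at 0.98 ± 0.12 (camera adjusted p = 0.00607, and adjusted p = 0.158 with an estimated correlation). Matrix and protease genes had 6 of 18 higher and 1 lower, with Mmp14 at 1.78 ± 0.10 (camera adjusted p = 0.0251, and adjusted p = 0.315 with an estimated correlation). The MHC class II and costimulation list had 4 of 12 higher, with H2-Aa at 0.39 ± 0.09, and 4 lower, with Cd80 (-2.51 ± 0.10) and Cd86 (-0.85 ± 0.10). Dendritic cell markers moved in both directions, with Kmo (2.93 ± 0.11) higher and Ccr7 (-2.24 ± 0.13) and Xcr1 (-1.98 ± 0.14) lower. Neutrophil markers had 3 of 14 higher, B lymphocyte markers 2 of 8 higher, with Cd79b at 1.31 ± 0.12, mast cell and basophil markers 1 of 9 higher, and fibroblast markers 1 of 12 higher and 1 lower. Adjusted over the list alone, counts differed in 14 of the 25 lists, by at most 2 genes. Cyclic loess normalization, chosen after seeing the data, moved the share of changed genes that were higher from 61.3% to 46.3%, and a fit of only these 4 arrays called 2603 genes, 1488 of them higher.

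Against IL-4/IL-13 alone, the addition of LPS went with higher inflammatory genes and with lower levels of some of the strongest IL-4/IL-13 responses. Il1a was 216-fold higher (log2 7.76 ± 0.16, adjusted p = 5.07e-12), followed by Slamf1 (7.29 ± 0.12), Cd69 (7.08 ± 0.10), Il1b (6.72 ± 0.11), Nos2 (6.51 ± 0.10) and the fungal and mycobacterial sensor gene Clec4e (6.49 ± 0.13). Retnla was 53.6-fold lower (-5.75 ± 0.19), followed by Rnf144b (-4.60 ± 0.13), Prrg1 (-4.55 ± 0.11), Gpr155 (-4.48 ± 0.13), Sesn1 (-4.07 ± 0.15) and Gprc5c (-4.03 ± 0.08). In limma, 2815 genes were higher and 4504 lower, 36.7% of the genes tested, and 1064 and 1160 differed at least 2-fold. The 29 STAT6-linked genes split into 12 higher and 11 lower (13 when adjusted over the list alone). Ccl24 (4.02 ± 0.11), Ccl22 (3.40 ± 0.10), Arg1 (2.03 ± 0.12) and Ccl17 (1.91 ± 0.17) were higher, Irf4 (-3.51 ± 0.15) and Mrc1 (-0.29 ± 0.08) were lower with Retnla, and Chil3 did not pass (-0.40 ± 0.17, adjusted p = 0.0984). That list's median (-0.08) and camera direction (up) differed in sign. NF-kB-driven genes had 28 of 29 higher, with Il6 (6.23 ± 0.14), Tnf (4.68 ± 0.08) and Cxcl2 (6.15 ± 0.15), and camera adjusted p = 6.63e-29, and adjusted p = 0.0167 with an estimated correlation. All 27 interferon-stimulated genes were higher, with camera adjusted p = 3.17e-29, and adjusted p = 0.142 with an estimated correlation. Of 14 IFN-gamma-inducible genes 12 were higher and 1 lower, with camera adjusted p = 5.8e-13, and adjusted p = 0.0205 with an estimated correlation. Il12b was higher by 1.06 ± 0.10.

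Feedback regulators had 16 of 19 higher and 1 lower, with Il10 at 4.82 ± 0.14 (camera adjusted p = 6.17e-13, and adjusted p = 0.0205 with an estimated correlation). Of 18 matrix and protease genes 10 were higher (12 when adjusted over the list alone) and 1 lower, with Serpinb2 at 5.49 ± 0.12 (camera adjusted p = 4.22e-06, and adjusted p = 0.142 with an estimated correlation). MHC class I genes had 10 of 12 higher and 1 lower (camera adjusted p = 3.66e-06, and adjusted p = 0.142 with an estimated correlation). Of 10 arginine and polyamine genes 6 were higher and 4 lower (camera adjusted p = 0.0427, and adjusted p = 0.404 with an estimated correlation). Growth factor genes had 8 of 27 higher, with Timp1 (4.59 ± 0.11), Inhba (3.95 ± 0.11) and Osm (2.79 ± 0.09), and 8 lower, with Igf1 (-0.61 ± 0.07). Cell cycle genes had 18 of 24 lower (19 when adjusted over the list alone), with Ccna2 at -2.31 ± 0.14 (camera adjusted p = 4.05e-06, and adjusted p = 0.251 with an estimated correlation). Of 21 fatty acid oxidation and TCA cycle genes 16 were lower and 1 higher, with Ppargc1b at -2.71 ± 0.11 (camera adjusted p = 6.01e-06, and adjusted p = 0.274 with an estimated correlation). Dendritic cell markers had 5 of 10 higher, with Fscn1 at 2.04 ± 0.13 (camera adjusted p = 0.0152, and adjusted p = 0.177 with an estimated correlation). Hdc (3.30 ± 0.13) and Dcn (1.73 ± 0.11) were the only mast cell and fibroblast markers to pass, both higher, and neutrophil markers had 2 of 14 higher and 2 lower. Cyclic loess normalization moved the share of differing genes that were higher from 38.5% to 49.7%.

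The 2 separate polarising treatments, compared with each other, differed in interferon-response, inflammatory and alternative activation genes. Under IFN-gamma/LPS, Il6 was 432-fold higher than under IL-4/IL-13 (log2 8.76 ± 0.14, adjusted p = 1.11e-12), followed by Cd69 (7.75 ± 0.10), Cxcl9 (7.13 ± 0.15), Il1a (7.00 ± 0.16), Nos2 (6.86 ± 0.10) and Il12b (6.82 ± 0.10). Retnla (-5.60 ± 0.19), Abcd2 (-4.66 ± 0.12), Rnf144b (-4.57 ± 0.13), Prrg1 (-4.44 ± 0.11), the caspase gene Casp6 (-4.41 ± 0.10) and Sesn1 (-4.40 ± 0.15) were lowest. In limma, 3097 genes were higher and 5205 lower, 41.6% of the genes tested, and 1259 and 1763 differed at least 2-fold. STAT6-linked genes had 19 of 29 lower and 6 higher, with Arg1 (-3.11 ± 0.12), Mrc1 (-1.54 ± 0.08), Chil3 (-1.36 ± 0.17) and Irf4 (-3.62 ± 0.15) lower, and camera adjusted p = 0.00129, and adjusted p = 0.177 with an estimated correlation. Ccl22 (4.76 ± 0.10) and Ccl24 (0.90 ± 0.11) were higher, and Ccl17 was not past the test (-0.08 ± 0.17). Among NF-kB-driven genes 26 of 29 were higher (27 when adjusted over the list alone), with camera adjusted p = 1.49e-24, and adjusted p = 0.0167 with an estimated correlation. Interferon-stimulated genes were all higher, 27 of 27 (camera adjusted p = 2.06e-25, and adjusted p = 0.161 with an estimated correlation). So were 12 of 14 IFN-gamma-inducible genes (camera adjusted p = 4.87e-14, and adjusted p = 0.0205 with an estimated correlation). Fatty acid oxidation and TCA cycle genes had 19 of 21 lower and 1 higher (camera adjusted p = 1.84e-06, and adjusted p = 0.257 with an estimated correlation). Glycolysis genes had 13 of 19 higher and 2 lower (camera adjusted p = 5.19e-05, and adjusted p = 0.181 with an estimated correlation). Sterol synthesis genes had 11 of 15 lower and 1 higher (camera adjusted p = 0.00378, and adjusted p = 0.142 with an estimated correlation). MHC class I genes had 9 of 12 higher and 2 lower (camera adjusted p = 0.000114, and adjusted p = 0.17 with an estimated correlation), and matrix and protease genes 8 of 18 higher and 3 lower (camera adjusted p = 0.00313, and adjusted p = 0.236 with an estimated correlation). Feedback regulators had 14 of 19 higher and 2 lower, with Socs3 at 4.97 ± 0.10 and Il10 at 3.83 ± 0.14 (camera adjusted p = 1.21e-07, and adjusted p = 0.041 with an estimated correlation). Of 24 cell cycle genes 20 were lower and 2 higher, with Ccna2 at -3.04 ± 0.14 (camera adjusted p = 1.83e-05, and adjusted p = 0.273 with an estimated correlation). Inhba was higher (4.19 ± 0.11) and Igf1 lower (-1.03 ± 0.07). Among markers of other cells, 5 of 10 dendritic cell markers were higher and 1 lower, with Fscn1 at 2.90 ± 0.13 and Ccr7 at 2.81 ± 0.13. Mast cell and basophil markers had 4 of 9 higher, with Hdc at 2.44 ± 0.13, neutrophil markers 3 of 14 lower and 1 higher, fibroblast markers 2 of 12 higher and B lymphocyte markers 1 of 8 lower. The share of differing genes that were higher was 37.3%, and 50.7% after cyclic loess normalization.

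Some genes stood higher in cells given LPS, IL-4 and IL-13 than in each of the other 3 groups, and others lower. By 3 limma tests per gene, 588 genes were highest and 358 lowest in that group, and 102 and 25 of them differed at least 2-fold from every other group. Il19 was lifted 18.2-fold over IFN-gamma/LPS (4.19 ± 0.13), 25.2-fold over IL-4/IL-13 (4.66 ± 0.13) and 29.9-fold over untreated cells (4.90 ± 0.13). Hbegf, which encodes an EGF receptor ligand, stood 9.10-fold and 17.3-fold above the IFN-gamma/LPS and IL-4/IL-13 groups, and the eosinophil chemoattractant gene Ccl24 8.72-fold and 16.2-fold. Against IFN-gamma/LPS, the other genes among the 10 with the widest margins were Zfp459 (4.25 ± 0.14), the thrombin receptor gene F2r (2.90 ± 0.20), the growth arrest gene Gadd45a (2.95 ± 0.15), the aquaglyceroporin gene Aqp9 (2.61 ± 0.11), Cxcl3 (2.57 ± 0.15), Id1 (2.55 ± 0.11) and the integrin gene Itgb8 (2.30 ± 0.12). Against IL-4/IL-13 their margins were 3.91 ± 0.14 for Zfp459, 3.07 ± 0.20 for F2r, 3.64 ± 0.15 for Gadd45a, 4.96 ± 0.11 for Aqp9, 2.85 ± 0.15 for Cxcl3, 2.42 ± 0.11 for Id1 and 4.02 ± 0.12 for Itgb8. By count, the list with most members among the 588 genes was the STAT6-linked one with 10 of 29, including Arg1 and Ccl17. The NF-kB-driven list followed with 7 of 29. The arginine and polyamine list, which shares Arg1 and Slc7a2 with the STAT6-linked one, had 4 of 10, and no test of these shares was run. Lowest in the group were the immune checkpoint gene Vsir, 6.82-fold under IFN-gamma/LPS and 8.28-fold under IL-4/IL-13, then N4bp2l1, Cytip, Bmp2, Pgm2l1, Pot1b, Enc1, the Toll-like receptor adaptor gene Ticam2, Gpr65 and Kif13b. Against IFN-gamma/LPS, Bmp2 stood at -2.31 ± 0.10, Ticam2 at -1.70 ± 0.10 and the acid-sensing receptor gene Gpr65 at -1.44 ± 0.10. Under cyclic loess normalization 79.8% of the 588 highest genes passed all 3 tests, and 76.5% did without LPS/IL-4/IL-13 array 1.

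**Figure D3:**
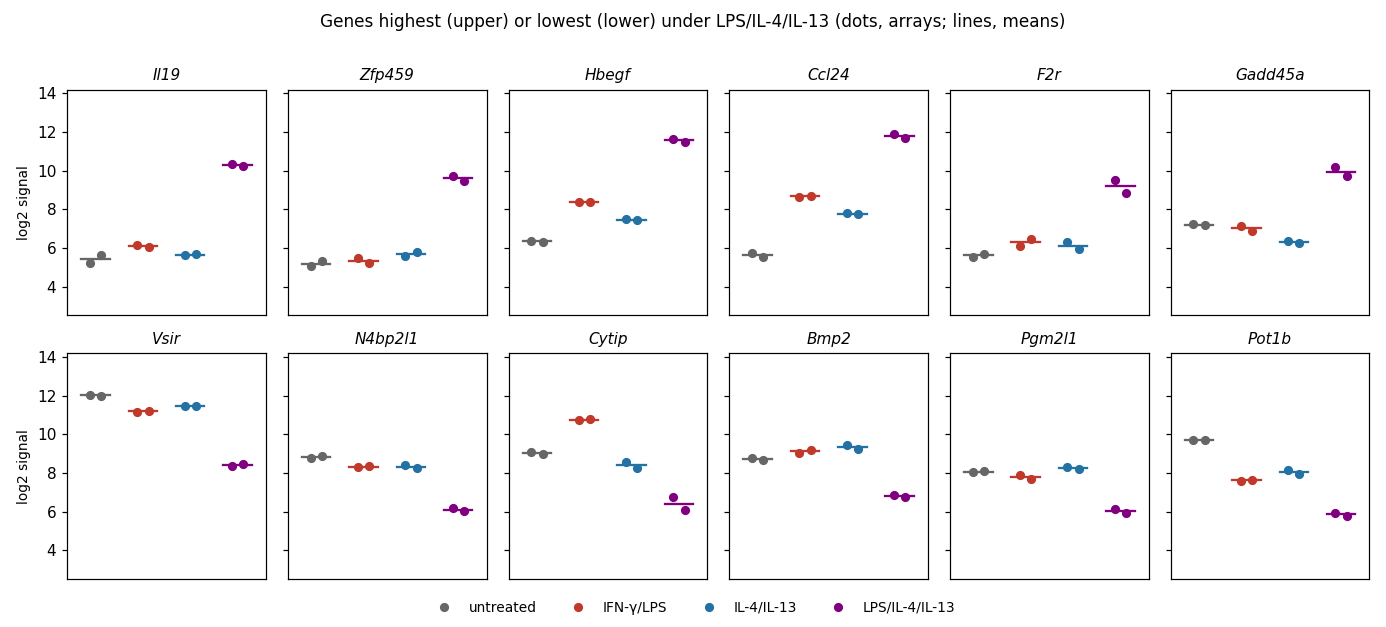
Log2 signal (vertical axis) on each of the 8 arrays for the 6 genes with the widest margins among those highest under LPS/IL-4/IL-13 and the 6 among those lowest, 1 point per array, with a line at each group mean. Il19 stood at 10.31 under LPS/IL-4/IL-13 and between 5.41 and 6.12 in the other groups, and Vsir at 8.42 against 11.19 to 12.03.

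Most genes changed by IFN-gamma/LPS changed the same way under LPS/IL-4/IL-13. Of the 4701 genes raised by IFN-gamma/LPS, among them Nos2, Cxcl9 and Il1a, 3011 (64.1%) were raised by LPS/IL-4/IL-13 too. Against IFN-gamma/LPS, 1041 of the 4701 stood lower, among them Il6, Il12b and Gbp4, and 333 stood higher. Of the 5656 genes that IFN-gamma/LPS lowered, 4552 (80.5%) were lowered under LPS/IL-4/IL-13, including Sesn1 and Slc40a1. Against IFN-gamma/LPS, 1704 of the 5656 stood higher and 257 lower. Of the 1561 genes raised by IL-4/IL-13, 831 (53.2%) were raised under LPS/IL-4/IL-13, including Pdcd1lg2 and Slc7a2, and 259 were lowered. Against IL-4/IL-13 alone, 602 of the 1561 stood lower, including Retnla and Irf4, and 367 stood higher. IFN-gamma/LPS raised 729 of the 1561 as well, Slc7a2 among them, so increases shared with the combination need not come from IL-4/IL-13. Of the 2459 genes that IL-4/IL-13 lowered, 1697 (69%) were lowered under LPS/IL-4/IL-13 and 425 were raised, Il1b among them. Against IL-4/IL-13 alone, 755 of the 2459 stood higher and 1079 lower. Genes were chosen and compared on the same arrays and the same untreated samples, so chosen values are extreme partly by chance and shrink in the next comparison. Part of the shared counts may come from the shared untreated arrays. Without untreated array 1, the genes raised by IFN-gamma/LPS and by LPS/IL-4/IL-13 numbered 1943. Those raised by IL-4/IL-13 and LPS/IL-4/IL-13 numbered 455 without untreated array 1, 474 without untreated array 2 and 490 without IL-4/IL-13 array 2, and those lowered by both 839, 1045 and 959.

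Across all genes, the fold changes of the 3 treatments against the same 2 untreated arrays were related, with genes not being independent replicates. IFN-gamma/LPS and LPS/IL-4/IL-13 had r = 0.895 and a covariance of 0.667, IL-4/IL-13 and LPS/IL-4/IL-13 had r = 0.438 and a covariance of 0.139, and IFN-gamma/LPS and IL-4/IL-13 had r = 0.339 and a covariance of 0.118. Unchanged groups simulated against shared controls gave r = 0.499 and a covariance of 0.0082, so the observed covariances lay 0.659, 0.131 and 0.110 above it. The simulated noise was independent per gene and left out shifts that follow signal level. Under IFN-gamma/LPS, IL-4/IL-13 and LPS/IL-4/IL-13 the median changes were 0.205, 0.145 and 0.165 in decile 4 of mean signal. In decile 8 they were -0.455, -0.115 and -0.275. Part of the excess covariance may come from such shifts. IFN-gamma/LPS and LPS/IL-4/IL-13 shared 3011 raised genes (953 from independent lists), with Nos2 and Il1a among them, and 4552 lowered genes (1435 from independent lists). IL-4/IL-13 and LPS/IL-4/IL-13 shared 831 raised genes (316) and 1697 lowered genes (624), and IFN-gamma/LPS and IL-4/IL-13 shared 729 raised genes (368), Slc7a2 and Ccl24 among them, and 1649 lowered genes (698), Slc40a1 among them. Unchanged groups shared 0 calls in 20 simulated fits, a value that leaves out the real effects and does not bound what shared controls add to them. The 2 untreated arrays are too few to split with replicates on both sides, so part of the excess over independent lists may come from the shared controls.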

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

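The tests in this part were chosen only after the results for named genes had been seen. Probe sets outside the named genes also differed from the untreated arrays, a signal in data that the comparisons do not use. Among 12146 probe sets with no gene symbol in the annotation used here, limma called 2383 under IFN-gamma/LPS (940 higher and 1443 lower, 19.6%), 198 under IL-4/IL-13 (65 higher and 133 lower) and 1774 under LPS/IL-4/IL-13 (600 higher and 1174 lower). Of those higher, 429, 22 and 240 were at least 2-fold above the untreated arrays, and the largest log2 fold changes were 7.51, 4.12 and 6.59. Among 1621 probe sets with several symbols, which may detect more than 1 gene, as related gene families often share sequence, the calls numbered 589 under IFN-gamma/LPS (161 higher and 428 lower), 52 under IL-4/IL-13 (18 higher and 34 lower) and 529 under LPS/IL-4/IL-13 (129 higher and 400 lower). Counting these as genes of their own gave 10780, 3855 and 9422 changed genes in the 3 comparisons against untreated cells. No gene name is given for any of them, and no explanation was tested.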

How the results depend on the processing

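Cyclic loess normalization, the crossed block and the added probe sets with several symbols were chosen only after seeing the data. The total counts of changed genes stayed within 1.5 times under quantile normalization, median centring, cyclic loess, the dim probe set filter, other variance models, the mean over probe sets, adjustment over all 6 comparisons and added probe sets, and no called gene turned to a call in the opposite direction under the 3 normalizations. With the mean over probe sets 3, 0, 4, 0, 1 and 1 called genes did. Which genes were called changed more than the totals. Of the 10357 genes called under IFN-gamma/LPS against untreated, 8093 were called again under quantile normalization and 7846 under cyclic loess. For LPS/IL-4/IL-13 these were 7418 and 7475 of 9099, and for IL-4/IL-13 3230 and 3533 of 4020. A fit of only the 4 arrays compared called 2603 genes between LPS/IL-4/IL-13 and IFN-gamma/LPS but 5805 for IL-4/IL-13 against untreated. The main fit called 3926 and 4020 with 1 spread shared by all groups. Replicate differences had an SD of 0.226 (IFN-gamma/LPS) and 0.233 (LPS/IL-4/IL-13), above 0.153 (untreated) and 0.179 (IL-4/IL-13). A shared spread lies between these, which goes with both changes in count, but the cause was not tested. The 4-array fit gave no value for the shared or extreme genes of the combination. A fold of at least 2 lowers counts by construction, to 3395, 487, 2768, 659, 2224 and 3022 for the 6 comparisons in the order reported. It leaves 102 highest and 25 lowest genes in the combination, with 798 and 1505 genes raised and lowered by both groups with LPS and 124 and 155 by both groups with IL-4/IL-13. Leaving out each array in turn, where the lone array was assumed to vary like the other groups, gave 2063 to 4876 changed genes for IL-4/IL-13 against untreated. It gave 1943 to 2900 genes raised by both groups with LPS, and 455 to 947 raised and 839 to 2052 lowered by both groups with IL-4/IL-13. The lowest of these 4 values came without untreated array 1, and the cause was not tested. Camera with a correlation estimated per list called 13 list tests against 63. Lists with an estimated correlation under the preset 0.01 lost strength too. For IFN-gamma/LPS against untreated, camera adjusted p went from 1.09e-19 to 0.0167 in the NF-kB-driven list (correlation -0.01). In the feedback regulator list (-0.048) it went from 2.38e-06 to 0.0529. A higher correlation therefore does not account for the change in these lists. With an estimated correlation, camera uses at most the 4 residual degrees of freedom, a limit that the preset correlation does not set. The adjusted p-values with an estimated correlation therefore do not measure correlation alone. How much each part adds was not tested. Fry, which asks another question, called 117. Fry turned the direction of 3 uncalled shifts, chemoattractant receptors under LPS/IL-4/IL-13 against untreated (adjusted p = 0.0331), macrophage identity against IL-4/IL-13 (0.0417) and phagocytosis genes between the single treatments (0.00807), all over members that go both ways. For IFN-gamma/LPS against untreated, Ciita turned from an uncalled -0.055 to 0.311 under quantile normalization (adjusted p = 0.0262). There Ccr2 turned under cyclic loess from a called decrease of -0.365 to an uncalled 0.030 (adjusted p = 0.865). Between the single treatments N4bp2l1 moved under cyclic loess from no difference to 0.341 (adjusted p = 0.00854). The cause was not tested in these 3 genes. Replicate numbers 1 and 2 recur in the labels, but they do not establish pairing with 2 arrays per group, and the replicate differences of the groups correlated between -0.358 and 0.217. With the replicate number as a block the 6 comparisons gave 10432, 3978, 9138, 3833, 7321 and 8307 changed genes, 588 highest genes became 583, and the list tests called 59. The crossed block gave 10813, 4748, 9567, 4404, 7699 and 8620. The planned addition of 16 before log2 was not run because the table is already on a log2 scale. Without detection calls, signal over background limits what can be said of dim genes, and saturation of bright genes was not tested.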

Other observations

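The gene lists of the next 2 paragraphs, and the tests of transcription at dim genes further on, were chosen only after the results had been seen. Iron handling genes moved with the treatments in both directions, 5 of 15 measured genes up and 8 down under IFN-gamma/LPS, 2 up and 5 down under IL-4/IL-13, and 5 up and 7 down under LPS/IL-4/IL-13. The transferrin receptor gene Tfrc, which takes up iron, rose under IL-4/IL-13 (log2 1.26 ± 0.12) and fell under IFN-gamma/LPS (-1.70 ± 0.12) and LPS/IL-4/IL-13 (-2.10 ± 0.12), a difference of -3.36 ± 0.12 between the 2 groups with IL-4/IL-13. The zinc and iron importer gene Slc39a14 rose by 1.24 ± 0.13 under IFN-gamma/LPS and by 3.28 ± 0.13 under LPS/IL-4/IL-13, where it stood higher by 2.04 ± 0.13. The haem-degrading enzyme gene Hmox1 fell in all 3 treated groups (-2.41 ± 0.08, -1.43 ± 0.08 and -0.87 ± 0.08). Prostaglandin and leukotriene genes had 5 of 16 up and 9 down under IFN-gamma/LPS and 5 up and 8 down under LPS/IL-4/IL-13. The prostaglandin E synthase gene Ptges rose by 3.62 ± 0.14 and 5.24 ± 0.14 and differed between these groups by 1.63 ± 0.14, while the prostaglandin-degrading enzyme gene Hpgd fell (-3.11 ± 0.08 and -2.66 ± 0.08) and the receptor gene Ptger4 stood lower under LPS/IL-4/IL-13 than under IFN-gamma/LPS (-1.64 ± 0.09).

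Some pattern recognition receptor genes differed between the 2 groups given LPS, in both directions, and no list test was run. Of 16 measured Toll-like receptor and adaptor genes, 7 were higher and 3 lower under LPS/IL-4/IL-13 than under IFN-gamma/LPS, and 6 did not pass. The LPS receptor gene Tlr4 fell under IFN-gamma/LPS (-0.90 ± 0.10) and rose under LPS/IL-4/IL-13 (0.67 ± 0.10), Tlr8 was higher in the latter by 1.21 ± 0.06, and the adaptor gene Ticam2, which links Tlr4 to interferon signalling, was lower (-1.70 ± 0.10). Tlr13, a sensor of bacterial ribosomal RNA, fell in all 3 treated groups (-3.72 ± 0.09, -1.81 ± 0.09 and -2.77 ± 0.09). Of 13 C-type lectin receptor genes 4 were higher, 2 lower and 7 did not pass between the 2 groups given LPS, and 7 were higher and 1 lower under LPS/IL-4/IL-13 than under IL-4/IL-13 alone. Clec4e fell under IL-4/IL-13 (-1.93 ± 0.13) and rose in both groups with LPS (4.50 ± 0.13 and 4.56 ± 0.13), and the beta-glucan receptor gene Clec7a rose under IL-4/IL-13 (0.91 ± 0.07) and LPS/IL-4/IL-13 (1.37 ± 0.07).

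Dim genes stood above the untreated arrays in every treatment. The median change of the 7975 dimmest genes was 0.185 under IFN-gamma/LPS, 0.135 under IL-4/IL-13 and 0.16 under LPS/IL-4/IL-13, and 0.037, 0.008 and 0.03 after quantile normalization. Olfactory, vomeronasal and taste receptor genes, 1212 genes taken as silent in macrophages, shifted too, by 0.13, 0.18 and 0.115. The last had a bootstrap interval of 0.10 to 0.13. An offset between the arrays at low signal would give such a shift. The intervals in this paragraph resampled genes, not arrays, so they leave out the spread between the arrays of a group. After quantile normalization the receptor genes stood at -0.001, 0.062 and -0.002, so part of their shift remained under IL-4/IL-13. Other dim genes of the same signal level lay 0.062 below the receptor genes under IL-4/IL-13 (excess -0.062, interval -0.071 to -0.046). No rise beyond the receptor genes was seen there. The receptor genes rose more than their signal level alone gives, so this reference cannot decide on transcription raised at the dim genes themselves. Under the LPS-containing treatments the excess was 0.064 and 0.058, too small to decide, so raised transcription at some dim genes stays open there too.

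The 2 replicate differences of IFN-gamma/LPS and of LPS/IL-4/IL-13 ran opposite to each other across genes, with a correlation of -0.358. After cyclic loess normalization the value was -0.278, just past the mark set in advance. That argued against an offset that depends on signal as the whole source. The value did move toward zero, so such an offset may add a part. A difference between replicates in the strength of the shared response was argued against by the value without that response, -0.355. A mixed-up number, a handling batch that crosses the numbers and chance each stay open with 2 arrays per group, and no biological explanation was tested.

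The 588 genes that were highest under LPS/IL-4/IL-13 could reflect technical offsets, a single array, or a response to the combination. After cyclic loess normalization 79.8% of them passed all 3 tests (85.4% after quantile normalization), just under the 80% set in advance as evidence against an offset. Without LPS/IL-4/IL-13 array 1 the share was 76.5% and without array 2 it was 90.1%, so neither technical source is excluded for the whole group. Without a group given LPS alone, a gene held down by IFN-gamma and a gene raised by LPS with IL-4/IL-13 cannot be separated here, which was not tested.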
